A study of Mus musculus with 5 samples.

How the data were processed

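Open chromatin was measured by ATAC-seq, in which the Tn5 transposase cuts accessible DNA and inserts sequencing adapters, in 5 libraries of mouse CD4 T cells. Per the labels' protocols, naive CD4 T cells were stimulated for 48 hours through CD3 and CD28, sorted by GFP, and 50000 cells were lysed for each reaction. The Eomes-GFP+ group (3 libraries) came from reporter mice in which GFP is made together with Eomes, with 2 mice pooled per library. The Eomes-KO group (2 libraries) came from single mice with floxed Eomes alleles and a Cre recombinase driven from Cd4 regulatory DNA. Whether these mice carried the reporter, and so whether their cells were selected on it, is not given in the sources used here. Genotype and pooling of mice differed together between the groups, and the labels give neither sex nor preparation date.

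The deposited table held 1 signal value per library for each of 67018 merged peaks. Per the submitters' processing notes, the tools were bcl2fastq, Trim Galore 0.6.5, FastQC 0.11.7, Bowtie2 2.2.9, MACS2, featureCounts and Subread 2.10.1, with the mouse build mm10. Their settings, the shift for the Tn5 insertion, the treatment of duplicate and mitochondrial reads and the rule for merging peaks are not given in the sources used here. Each value of a library was a whole multiple of the same step within 0.01 read, for 100% of the values, so the deposited signal was a read count divided by 1 size factor per library. Size factors recomputed from the recovered reads by the median-of-ratios rule of DESeq2 1.42.0 ran from 0.901 to 1.09 and equalled the steps to the digits printed. Coordinates of the 67018 rows equalled those of the deposited peak list, which has 4 columns and gave positions only. The knockout columns are numbered 2 and 3 while the titles number those samples 1 and 2, so both were used as replicates of the group (KO2 and KO3) without a sample number.

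Recovered reads in peaks numbered 41430694, 42050908 and 41299282 in Eomes-GFP+ replicates 1, 2 and 3, and 38542673 and 39297588 in KO2 and KO3. The median peak held 163 to 206 reads per library. No molecular identifiers were used here, so the floor of 3 reads set for a peak without reads covers counting error only.

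The test planned before the data were examined was edgeR on raw counts, or limma if the values proved to be normalized. The deposited values are scaled, so limma 3.58.1 in R 4.3.3 was used on log2(value + 1), with a mean-variance trend, robust variance moderation, the group as the only term and Benjamini-Hochberg adjustment over all tested peaks at 0.05. Peaks needed at least 10 scaled reads in at least 2 libraries, which left 66969 and removed 49. Log2 fold changes are Eomes-KO minus Eomes-GFP+ on the log2(value + 1) scale, which understates changes of low peaks, and errors of log2 folds are standard errors. The quasi-likelihood test of edgeR 4.0.16 on the recovered reads, run with TMM factors after the data were seen, called 26126 peaks. Data were simulated for Eomes-KO minus Eomes-GFP+ over 66969 peaks, with 50 peaks changed at each fold. In these, limma recovered 32% of peaks changed 1.2-fold, 82% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and called 14 unchanged peaks.

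Peaks were assigned to protein-coding genes of a RefSeq table for GRCm38.p6, the assembly behind mm10, which gives gene spans without strand, exons or transcription start sites. A peak within 1 kb of either end of a gene span was called a gene-end peak and given to that gene, and others went to the nearest span within 100 kb. Gene-end peaks take the place of the planned promoter peaks, and assignment by distance does not show that a peak acts on the gene. Of 515 entries in 18 gene lists fixed beforehand, 514 matched the table. The lists were type 1 and cytotoxic, Th17, Th2, regulatory T, naive and memory, activation, inhibitory receptors, survival and apoptosis, respiratory chain subunits, mitochondrial biogenesis and dynamics, mitochondrial ribosome, glycolysis, cell cycle, and markers of CD8 T cells, of NK, NKT and gamma-delta T cells, of B cells, of myeloid and dendritic cells, and of erythroid and stromal cells. Lists were tested with camera (preset correlation 0.01, and an estimated one) and fry, adjusted over the 18 lists. For camera, gene-end versions of a list were still set against all other tested peaks. Gene-end peaks as a class had a median log2 fold of 0.04, against -0.04 inside genes and 0.02 between genes. Part of an upward camera call of gene-end peaks can therefore reflect that class. With an estimated correlation, camera p can rise even where the estimate lies below the preset. Medians of gene-end peaks, 1 per gene, were also set against 10000 random lists matched on peak height.

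Peaks named in the text follow a rule fixed beforehand: all tested peaks within 50 kb of Eomes; per direction, the 12 with the smallest p whose groups do not overlap; per list and direction, up to 4 genes by their called peak with the smallest p; and the tallest peak of genes chosen singly, among them Tbx21, Ifng, Bcl2, Bcl2l11, Ppargc1a, Tfam, Tcf7 and Foxp3. Not every peak that the rule selects is described. No tested peak was assigned to Foxp3. Peaks described around Cd4 and within 10 Mb of Eomes or Ifng beyond that rule were chosen after their values were seen. Alternatives covered scaling, test, filter, threshold, pseudocount, gene assignment, single libraries left out and regions in doubt. Motif content and corrections for GC content need a genome sequence, which was not used here.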

Results

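The data comprised 5 ATAC-seq libraries of mouse CD4 T cells stimulated for 48 hours, 3 from cells sorted for a GFP reporter of Eomes and 2 from Eomes-knockout cells. Eomes is a T-box transcription factor of cytotoxic and memory lymphocytes. The comparison addresses how chromatin accessibility differs between activated CD4 T cells sorted for the Eomes reporter and Eomes-knockout cells. Whether the knockout cells were selected on the reporter is not given, and pooling of mice differed with genotype. For every call below, loss of Eomes therefore cannot be told apart from selection of Eomes-expressing cells or from pooling. Reads in peaks numbered 38542673 to 42050908 per library.

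Libraries of a group resembled each other closely. Across 66969 peaks, which are not independent replicates, Spearman correlations were 0.992 to 0.993 among Eomes-GFP+ libraries, 0.990 between the knockout libraries and 0.954 to 0.961 across groups. The first principal component carried 79.5% of the variance and separated the groups. Mitochondrial DNA gave 15.3 ± 0.636% of reads in peaks in Eomes-GFP+ (SD, n = 3) and 20.3 ± 0.580% in Eomes-KO (SD, n = 2). The exact two-sided permutation test of that share gave p = 0.1, the smallest value that 3 against 2 libraries allow. The X chromosome held 1.35% of reads in nuclear peaks in both groups.

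At Eomes itself (chromosome 9, 118478186 to 118486132, mm10), accessibility was lower in the knockout but not lost. The tallest called peak of the locus, which overlaps the gene span (118478419 to 118479629), held 1007, 1018 and 987 scaled reads in Eomes-GFP+ replicates 1, 2 and 3, and 688 and 724 in KO2 and KO3. Its log2 fold was -0.51 ± 0.0558 (limma adjusted p = 1.15e-08). The peak across that end of the gene (118477476 to 118478273) had a log2 fold of -0.39, and those 1134 bp and 26571 bp outside it had -0.83 and -0.58. Peaks 1297 bp and 2651 bp beyond the other end were not called, at -0.14 and -0.12, and both were called lower with scaling by library size (limma adjusted p = 0.00161 and 0.000222) or by nuclear reads (0.0291 and 0.0111). The latter was also called with loess offsets (0.0353) and without KO2 (0.0182). Of 13 tested peaks within 50 kb, 7 were lower, 0 higher and 6 not called, and 3 of the lower ones were assigned to the neighbouring gene Golga4, at -1.48, -1.08 and -0.20. The call of the last (limma adjusted p = 0.0388) was lost without Eomes-GFP+ replicate 1, 2 or 3 or without KO2 (0.0668, 0.136, 0.0658 and 0.312), with loess offsets (0.0598) and with the DESeq2 Wald test (0.164). Which exons the floxed allele removes is not given in the sources used here, so these peaks do not decide the genotype labels. Within 10 Mb of Eomes, 19 of 702 peaks changed at least 4-fold, 13 of them over 5 Mb away, against a median of 2 per 20 Mb window.

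Peaks assigned to genes of the type 1 and cytotoxic programme were more often lower than higher in the knockout. Of 258 peaks assigned to 38 genes of this list, 114 were lower, 25 higher and 119 not called, and 29 of the lower ones changed at least 2-fold against 0 of the higher ones. Adjusted over the list alone, 119 were lower and 27 higher, and 151 were lower and 5 higher with scaling by library size and 129 and 12 by nuclear reads. Without regions in doubt, among them 10 Mb on each side of Eomes, 105 were lower and 24 higher. Leaving out 10 Mb on each side of Ifng as well gave 96 and 24, with a median log2 fold of -0.15 against -0.19 before. Called peaks were only lower at 15 genes, only higher at 4 and in both directions at 14. The peak across an end of Ifng, which encodes the cytokine interferon gamma, fell from 208 ± 2.83 (SD, n = 3) to 43.6 ± 7.35 scaled reads (SD, n = 2), a log2 fold of -2.24 ± 0.140 (chromosome 10, 118440693 to 118441238; limma adjusted p = 6.53e-14). Within 100 kb of Ifng 17 peaks were tested, of which 9 were lower, 5 of them at least 2-fold, and 0 higher. The tallest peak assigned to Ifng, 21291 bp away, had a log2 fold of -0.32. The surroundings of Ifng also held other large changes: within 10 Mb, 10 of 631 peaks changed at least 4-fold, and 3 of these lay within 100 kb of the gene.

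A peak 11446 bp from Runx3, a transcription factor of cytotoxic T cells, had a log2 fold of -2.09 (chromosome 4, 135108443 to 135109199), and one 55117 bp from Zeb2, a transcription factor of effector lymphocytes, had -2.18 (chromosome 2, 45172559 to 45173348). Runx3 had 9 lower and 0 higher peaks, and Zeb2 had 8 and 0. A peak near Fasl, the ligand of the death receptor Fas, had a log2 fold of -0.89. Peaks of Hopx (0.85), Klrc1 (0.56) and Il12rb1 (0.30) went the other way. Of 10 Hopx peaks 3 were higher and 1 lower, with log2 folds from -1.84 to 0.85. The tallest peak of Tbx21, which encodes T-bet, lay across an end of the gene and had a log2 fold of 0.05 ± 0.0642 (limma adjusted p = 0.569).

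The mean log2 fold of the type 1 list differed from that of other peaks by -0.26 (camera adjusted p = 7.37e-06; adjusted p = 0.398 with an estimated correlation). Fry, which asks whether peaks moved on balance one way, gave an adjusted p of 0.00942. That call was lost without Eomes-GFP+ replicate 1 or 3 (fry adjusted p = 0.0658 and 0.0516) and with the replicate block (0.236). The tallest gene-end peaks of 30 type 1 genes, 1 per gene, had a median log2 fold of -0.24, while 95% of matched random lists lay between -0.11 and 0.07. Over all 40 gene-end peaks of these genes the median was -0.07, with 15 lower, 6 higher and 19 not called. Camera on those peaks gave an adjusted p of 0.0417 (0.281 with an estimated correlation). Among markers of other cells, 3 of 6 CD8 T cell peaks were lower and 1 higher (3 and 2 adjusted over the list alone), and 9 of 31 peaks of NK, NKT and gamma-delta T cells were lower and 4 higher (9 and 4; 15 and 3 with scaling by library size).

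**Figure D1:**
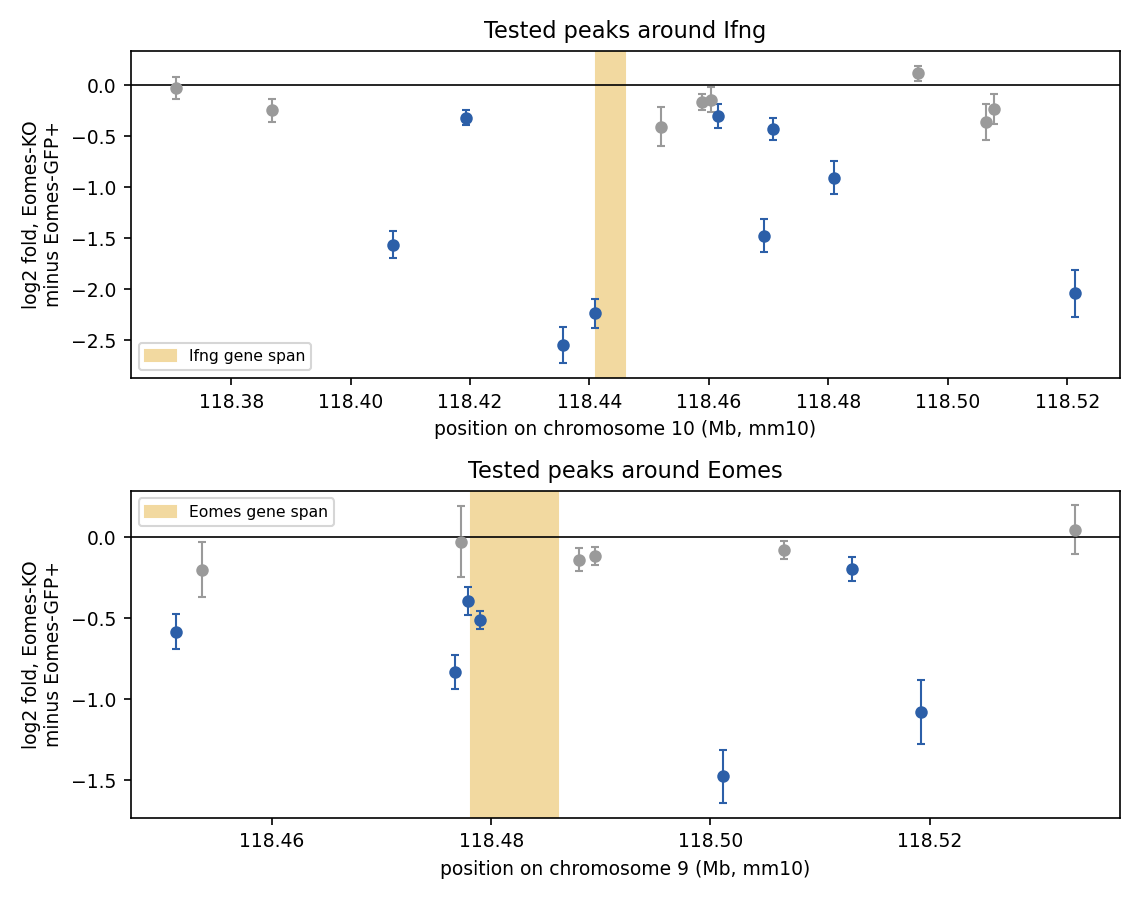
Log2 fold change (Eomes-KO minus Eomes-GFP+, vertical axis) of each tested peak by its position in Mb (horizontal axis) around Ifng and Eomes; points are estimates from 3 against 2 libraries, bars standard errors, blue points called lower, grey points not called, and shading the gene span. The 9 called peaks around Ifng and the 7 around Eomes all lie below 0.

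Genes of inhibitory receptors moved in both directions, with 47 of 145 peaks higher and 26 lower, although with scaling by library size, which moved the median log2 fold of all peaks from 0.01 to -0.14, 30 were higher and 44 lower. Adjusted over the list alone, 50 were higher and 28 lower. A peak 5604 bp from Ctla4, a receptor that restrains T cell activation, rose from 452 ± 24.7 (SD, n = 3) to 1392 ± 65.8 scaled reads (SD, n = 2), a log2 fold of 1.62 ± 0.0644 (chromosome 1, 60902449 to 60903421; limma adjusted p = 1.63e-18). Another Ctla4 peak, 32702 bp away, had -0.49. A peak inside Tigit rose by 1.03 on the log2 scale (chromosome 16, 43661545 to 43662156), and peaks near Pdcd1 and Lag3 had log2 folds of 0.53 and 0.62. The Lag3 peak lies on chromosome 6 close to Cd4, where 5 of 6 peaks rose more than 4-fold. Btla, another inhibitory receptor, had a gene-end peak at -0.96, although 6 of its 14 peaks were higher and 4 lower. Peaks inside Tox and Tox2, transcription factors linked to T cell exhaustion, had -0.60 and -1.09. The list's mean lay 0.14 above other peaks (camera adjusted p = 0.0278; adjusted p = 0.390 with an estimated correlation). The camera call was lost with gene-end peaks alone (adjusted p = 0.228), with links within 20 kb (0.0967) and without KO2 (0.0637).

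Peaks near other T cell genes changed both ways, and camera called none of the activation, naive and memory, Th17, Th2 and regulatory T lists. Among activation genes 93 of 270 peaks were higher and 70 lower (94 and 72 adjusted over the list alone), which turned to 34 and 102 with scaling by library size and 59 and 81 by nuclear reads. A peak inside Cd44, an adhesion receptor of activated cells, fell from 366 ± 24.6 (SD, n = 3) to 84.4 ± 7.66 scaled reads (SD, n = 2; chromosome 2, 102849748 to 102850241; log2 fold -2.10 ± 0.110). Peaks of Prdm1, which encodes the repressor Blimp-1, and of Il2ra, a subunit of the interleukin 2 receptor, had log2 folds of -0.72 and -1.59. Of 17 peaks each, Cd44 had 5 higher and 6 lower, and Il2ra 6 higher and 5 lower. Peaks of Il2, Batf, Cd40lg and Cd69 had 0.53, 0.84, 0.54 and 0.29.

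Naive and memory genes had 149 lower and 86 higher peaks of 461 (155 and 90 adjusted over the list alone; 228 and 37 with scaling by library size and 178 and 58 by nuclear reads). Peaks of Foxo1, a transcription factor of naive T cells, of Slamf6 and of S1pr1 had log2 folds of -1.51, -1.10 and -1.25. Peaks of Ets1, Dapl1, Id3 and Cxcr5 had 0.81, 1.16, 0.83 and 0.85. Most calls at 2 of these genes went the other way. Ets1 had 4 higher and 12 lower of 38 peaks, and Cxcr5 1 and 7 of 11. Dapl1 had 8 higher and 0 lower of 13 peaks, and Id3 7 and 0 of 11. The tallest peak of Tcf7, a transcription factor of naive and memory T cells, had a log2 fold of 0.11 ± 0.0413 (limma adjusted p = 0.0410). That call was lost without Eomes-GFP+ replicate 1 or 3 or KO3 (adjusted p = 0.132, 0.101 and 0.287), with the DESeq2 Wald test (0.226), and with scaling by TMM (0.0511), nuclear reads (0.367) or loess offsets (0.317), and the value turned to -0.04 with scaling by library size.

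Of 173 Th17 peaks 58 were higher and 43 lower (61 and 44 adjusted over the list alone), which turned to 30 and 64 with scaling by library size and 43 and 50 by nuclear reads. Rora, a nuclear receptor of Th17 cells, had peaks at 1.08 and -2.64, Csf2, which encodes the cytokine GM-CSF, had a gene-end peak at 0.73, and peaks of Stat3 and Maf had -0.55 and -0.95. Th2 genes had 21 lower and 14 higher of 66 peaks (21 and 16 adjusted over the list alone; 27 and 7 with scaling by library size), with Gata3, the main Th2 transcription factor, at -0.74 and Il1rl1 at 0.70. Regulatory T cell genes had 46 lower and 33 higher of 153 peaks (46 and 35; 65 and 20 with scaling by library size), with Il10, an anti-inflammatory cytokine gene, at -0.69 and Nrp1 at 1.07. Another Nrp1 peak, called lower, ran from -1.01 to -0.73 across the alternatives. Camera adjusted p was 0.451 for activation, 0.234 for naive and memory, 0.349 for Th17, 0.913 for Th2 and 0.887 for regulatory T. Fry, in contrast, called naive and memory (adjusted p = 0.00942) and regulatory T (0.0212) downward. The naive and memory call was lost without Eomes-GFP+ replicate 1 or 3 (0.0658 and 0.0537). The regulatory T call was lost without replicate 2 or 3 (0.0817 and 0.0577).

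**Figure D2:**
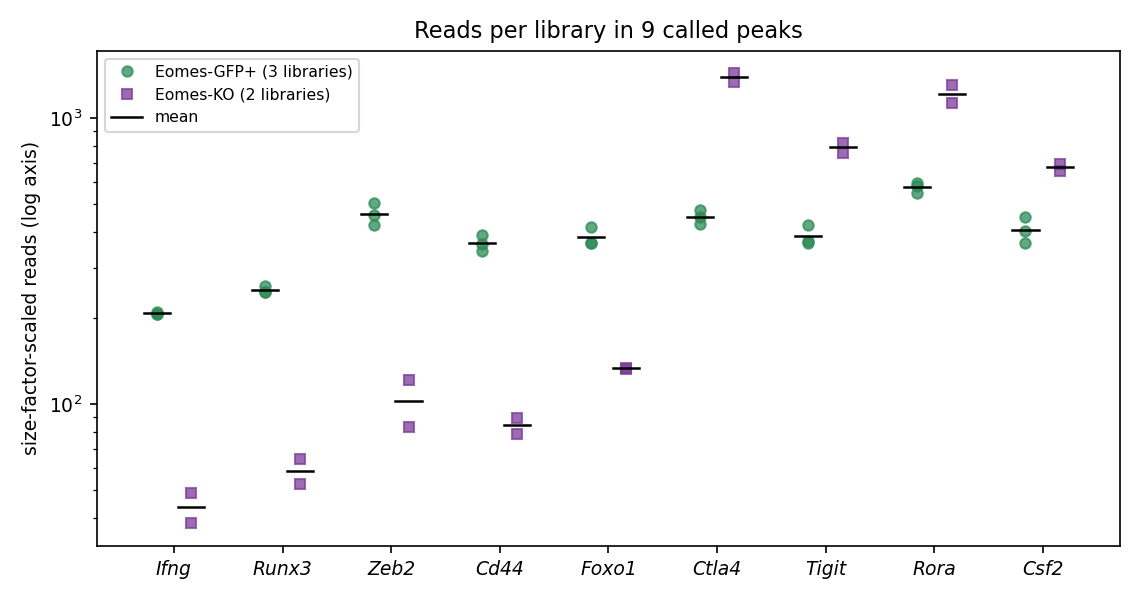
Size-factor-scaled reads (log axis) in 9 called peaks, named by their assigned gene, for each of 3 Eomes-GFP+ libraries (circles) and 2 Eomes-KO libraries (squares), with group means as lines. At each peak the groups do not overlap, the Ifng peak falling from 208 to 43.6 and the Ctla4 peak rising from 452 to 1392.

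Genes of mitochondrial function, a subject of the series title, showed small shifts. Peaks of respiratory chain subunits were higher 34 times and lower 12 times of 152 (31 and 12 adjusted over the list alone), but 11 and 33 times with scaling by library size and 22 and 17 by nuclear reads. Those of the mitochondrial ribosome were higher 46 times and lower 19 times of 176 (45 and 19), but 16 and 41 times with scaling by library size and 28 and 25 by nuclear reads. Relative to the median of all peaks, the medians of these lists were 0.07 and 0.06 with either scaling. This was nearly fixed in advance, since such scaling moves almost all log2 folds alike. The means of both lists lay 0.11 above other peaks (camera adjusted p = 0.0278 for both; adjusted p = 0.398 and 0.337 with an estimated correlation). Library size ended both camera calls (adjusted p = 0.360 and 0.292), as did nuclear library size (0.0745 for both), loess offsets (0.103 and 0.0821), the replicate block (0.152 and 0.138) and leaving out KO2 (0.103 and 0.0666). Camera called both lists upward with gene-end peaks alone, set against all other tested peaks (adjusted p = 0.00274 and 0.00189; adjusted p = 0.267 for both with an estimated correlation). It also did so with links within 20 kb (adjusted p = 0.00238 and 0.00463; adjusted p = 0.262 and 0.244 with an estimated correlation).

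Gene-end peaks of respiratory chain subunits and of the mitochondrial ribosome each had a median log2 fold of 0.08, at percentiles 97.99 and 98.15 of random lists matched on peak height, whose medians were 0.05. In the same comparison activation lay at percentile 99.9, mitochondrial biogenesis at 99.0, survival at 98.9, Th17 at 97.1 and cell cycle at 0.960. Inhibitory receptors, glycolysis, regulatory T, naive and memory, Th2, myeloid and erythroid lists lay between 3.26 and 80.9, without adjustment for the number of lists. Among peaks changed at least 2-fold, 4 of the respiratory chain were lower and 1 higher, and 2 of the mitochondrial ribosome were lower and 4 higher. A peak inside Ndufs4, a subunit of complex I, had a log2 fold of -2.44 (chromosome 13, 114304466 to 114305200), and one 40415 bp from Uqcrfs1, a subunit of complex III, had -1.96. Another Uqcrfs1 peak, called higher, ran from 0.81 to 1.04 across the alternatives. Peaks near Mrpl32 and Mrpl17, genes of mitochondrial ribosomal proteins, had 1.44 and 1.26. Mitochondrial biogenesis and dynamics had 46 higher and 31 lower of 212 peaks (43 and 31 adjusted over the list alone), turning to 12 and 65 with scaling by library size and 23 and 37 by nuclear reads (camera adjusted p = 0.250). With gene-end peaks alone, set against all other tested peaks, camera called this list upward (adjusted p = 0.0118; adjusted p = 0.357 with an estimated correlation). A peak inside Ppargc1b, a coactivator of mitochondrial biogenesis, had -1.84. The tallest peak of its relative Ppargc1a had -0.22 (limma adjusted p = 0.00930), a call lost with the DESeq2 Wald test (adjusted p = 0.0658) and without KO2 (0.0976). That of Tfam, which packages mitochondrial DNA, had a log2 fold of 0.04 ± 0.0492 (limma adjusted p = 0.601).

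Survival and apoptosis genes were split, with 46 higher and 44 lower of 216 peaks (47 and 45 adjusted over the list alone; camera adjusted p = 0.887), and 17 were higher and 75 lower with scaling by library size and 29 and 54 by nuclear reads. With gene-end peaks alone, set against all other tested peaks, camera called the list upward (adjusted p = 0.0138; adjusted p = 0.267 with an estimated correlation). Part of this call can reflect the higher level of gene-end peaks as a class. The tallest peak of Bcl2l11, which encodes the pro-apoptotic protein Bim, fell from 1093 ± 9.04 (SD, n = 3) to 630 ± 96.1 scaled reads (SD, n = 2; chromosome 2, 128152377 to 128153895; log2 fold -0.80 ± 0.0677). Bcl2, which opposes cell death, had peaks at -0.96 and 0.58, and its tallest peak had 0.18, a call lost with scaling by library size (limma adjusted p = 0.432). Its relative Bcl2l1 had peaks at -1.26 and 0.35. Glycolysis had 21 higher and 26 lower of 136 peaks (21 and 25 adjusted over the list alone, 6 and 54 with scaling by library size and 11 and 30 by nuclear reads). A peak of Hk2, a hexokinase gene, had -0.50 and one of Hif1a 0.63, although 2 of 18 Hif1a peaks were higher and 5 lower. Cell cycle genes had 19 higher and 20 lower of 118 (19 and 20; 5 and 54 with scaling by library size and 12 and 27 by nuclear reads), with the cyclin genes Ccnd2 at 0.68 and Ccnd3 at -1.02 (camera adjusted p = 0.913 for glycolysis and 0.617 for cell cycle).

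Several lists had a median above 0 and a mean below it: activation (0.07 and -0.02), survival (0.03 and -0.05), mitochondrial biogenesis (0.07 and -0.01), Th2 (0.02 and -0.06), glycolysis (0.01 and -0.03), cell cycle (0.01 and -0.02) and erythroid and stromal markers (0.01 and -0.03). Fry gave a downward direction to activation (adjusted p = 0.0309), Th2 (0.0309) and survival (0.00942), whereas camera ranked activation and survival upward without a call. These 3 fry calls were lost without Eomes-GFP+ replicate 1 (adjusted p = 0.146, 0.102 and 0.0658) or 3 (0.206, 0.234 and 0.0516). With the replicate block each had 0.236, but there fry called no list at all (lowest adjusted p 0.220), so that loss is not informative. Activation also lost its call without replicate 2 (0.125) and with loess offsets (0.0726), and survival without KO2 (0.0538). With gene-end peaks alone fry turned upward for activation (adjusted p = 0.0878) and survival (0.0167), and gave 0.0878 downward for Th2. Glycolysis was likewise upward by camera and downward by fry (adjusted p = 0.0947; 0.00539 with scaling by library size), and mitochondrial biogenesis and cell cycle were upward by both despite means below 0, but fry turned downward for both with scaling by library size (adjusted p = 0.00947 and 0.00539) or by nuclear reads (0.372 and 0.0322). Camera ranked Th2 and the erythroid and stromal markers downward despite medians above 0, the latter with a mean 0.02 above that of other peaks.

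**Figure D3:**
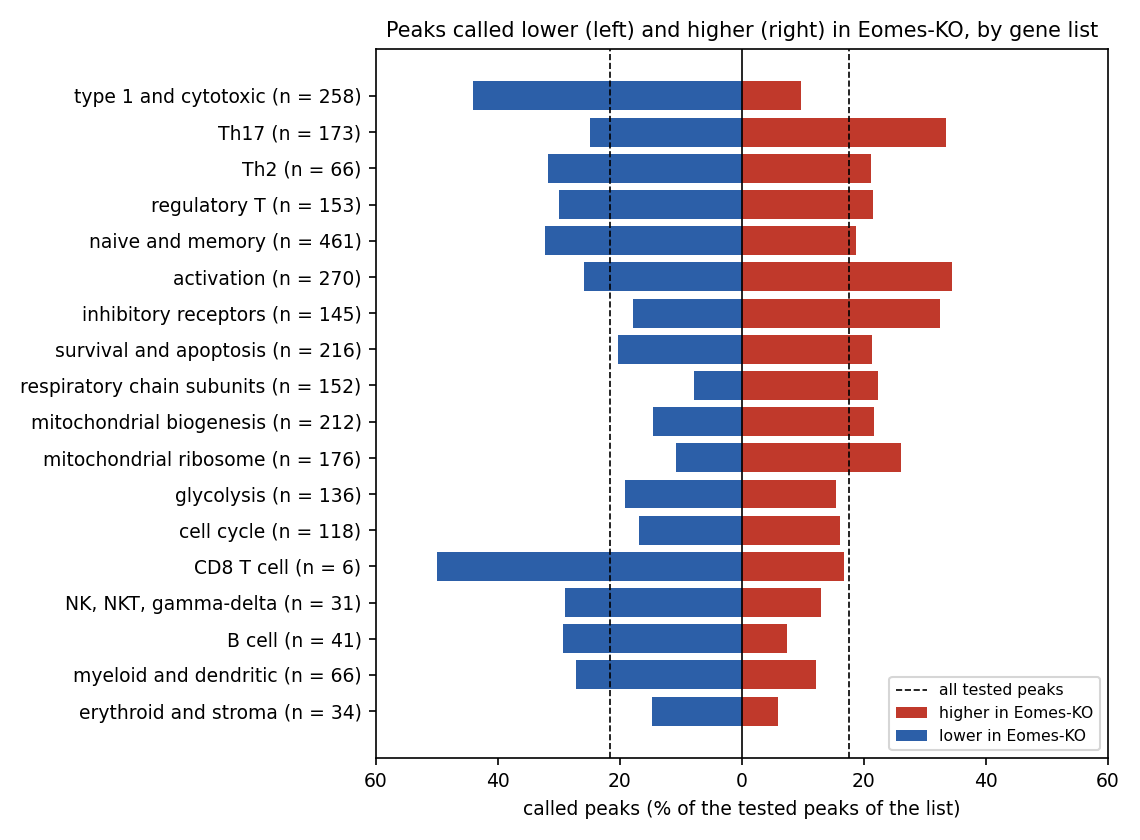
Share of the tested peaks of each gene list called higher (red, right) or lower (blue, left) in Eomes-KO, in percent; dashed lines mark the shares among all tested peaks and n is the number of peaks. The type 1 and cytotoxic list has 114 lower peaks against 25 higher, and the mitochondrial ribosome list 19 against 46, which turns to 41 against 16 with scaling by library size.

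Markers of other cell types were lower more often than higher, as were all tested peaks (14542 lower and 11814 higher of 66969). B cell markers had 12 lower and 3 higher of 41 peaks (11 and 2 adjusted over the list alone; 16 and 2 with scaling by library size), myeloid and dendritic markers 18 and 8 of 66 (18 and 8; 33 and 5), and erythroid and stromal markers 5 and 2 of 34 (5 and 2; 14 and 2). A peak inside Itgax, which encodes the integrin CD11c, had a log2 fold of -2.16, and peaks of Tyrobp, an adaptor of NK and myeloid receptors, had -1.79 and 0.26, the latter not called with scaling by library size. Camera adjusted p was 0.275 for B cell, 0.275 for myeloid and dendritic, 0.913 for erythroid and stromal, 0.277 for CD8 T cell and 0.275 for NK, NKT and gamma-delta T cell markers. In that order, fry adjusted p was 0.00942, 0.0215, 0.185, 0.0215 and 0.0309, all downward. The fry calls were lost without Eomes-GFP+ replicate 1 (0.0658, 0.0742, 0.102 and 0.120 for B cell, myeloid, CD8 and NK-lineage markers). They were also lost without replicate 3 (0.0537, 0.0836, 0.0516 and 0.0537). With gene-end peaks alone camera called the myeloid and dendritic list (adjusted p = 0.0126; adjusted p = 0.406 with an estimated correlation).

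Genome-wide, 26356 of 66969 peaks (39.4%) were called by limma, 14542 lower and 11814 higher in the knockout. Large changes were mostly losses, with 2223 peaks at least 2-fold lower against 701 higher. The groups did not overlap at 59.6% of peaks, where chance gives 20%. With scaling by library size, which counts mitochondrial reads, 24974 were lower and 5115 higher. With nuclear reads alone 17408 were lower and 7949 higher. The DESeq2 Wald test called 16028 peaks, 9731 lower and 6297 higher.

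Among peaks with the smallest p, losses lay inside Inpp4a, a phosphoinositide phosphatase gene (log2 fold -3.81; chromosome 1, 37327177 to 37327903), inside Itga2, which encodes an integrin (-2.20), and inside Fbxl17 (-3.00) and Mogat1 (-2.45). Others lay near Pik3ap1 (-3.01), Adh6a (-1.71), Sos1 (-1.22) and Gadd45g (-1.23). Gains lay near Otud1 (1.79), Tespa1 (1.46), Peli1 (1.68) and Cep43 (1.16), and inside Vps13d (0.86) and Sh3rf1 (1.22). Very large changes also lay at Cd4 and on chromosome 9 beyond Eomes. A peak inside Cd4 (chromosome 6, 124884917 to 124886939) rose from 1043 ± 55.2 (SD, n = 3) to 7430 ± 352 scaled reads (SD, n = 2), a log2 fold of 2.83. On chromosome 9, a peak inside Lztfl1 (123716350 to 123716550) had 176 ± 14.4 scaled reads in Eomes-GFP+ and 0 in both knockout libraries, at least 106-fold lower against a floor of 3 reads over the group. A peak near Ccr1 (3.51) and one inside Slc6a20b (-3.49) lie in the same region. A peak assigned to Mid1 on X (2.21) and one assigned to Gm52481 on Y (2.97) also rose. Both genes had calls in both directions, with 10 higher and 2 lower of 25 Mid1 peaks and 17 higher and 5 lower of 41 Gm52481 peaks.

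**Figure D4:**
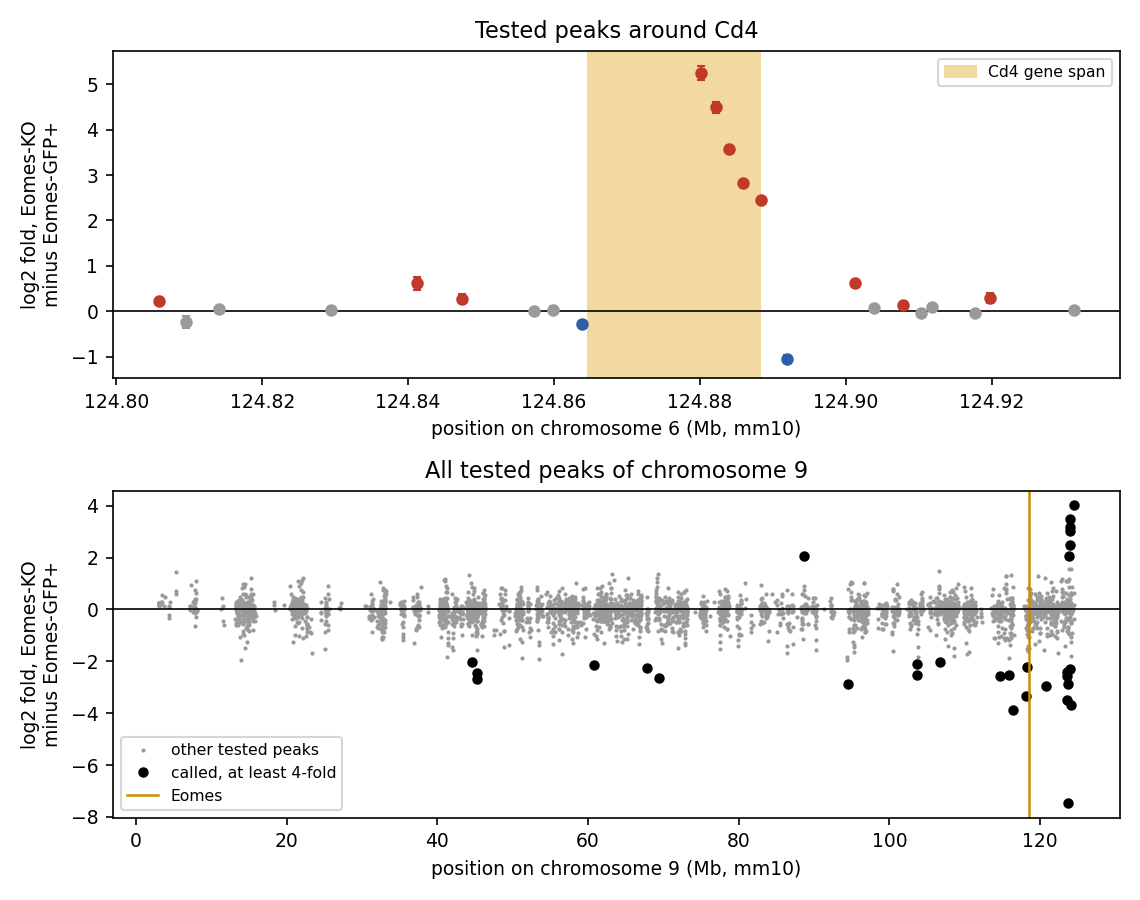
Log2 fold change (Eomes-KO minus Eomes-GFP+, vertical axis) by position in Mb for tested peaks around Cd4, with standard error bars and the gene span shaded, and for all tested peaks of chromosome 9, where black points are called and at least 4-fold and the line marks Eomes. The 5 raised Cd4 peaks lie between 2.45 and 5.25.

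Losses were rarer at gene ends than elsewhere, but more frequent there with scaling by library size. Gene-end peaks made up 15.3% of the lower calls against 21.1% of tested peaks (odds ratio 0.613, 95% interval 0.583 to 0.644; Fisher's exact test over peaks, which are not replicates, two-sided p = 2.08e-89), and 21.4% of the higher calls (odds ratio 1.02, p = 0.433). Inside genes 7563 of 29562 peaks were lower and 4580 higher, and between genes 4758 and 4695 of 23203. Gene-end peaks were taller, with a median of 870 scaled reads against 151 inside genes and 150 between genes. The tallest 13394 peaks leaned upward (3494 higher, 1450 lower), so position and peak height overlap here. With scaling by library size the odds ratio turned to 1.24 for lower calls, and it was 0.740 with nuclear reads and 0.783 with loess offsets. For higher calls it was 0.228 with library size, 0.526 with nuclear reads and 0.540 with loess offsets. For higher calls it was 0.796 without Eomes-GFP+ replicate 1, 0.809 without replicate 3, 0.815 without KO3 and 1.18 without KO2.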

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

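The tests in this part were chosen after the results were seen, although loess offsets had been planned as an alternative before the data were examined. Mitochondrial reads, a signal outside the nuclear peaks, stood above the level of the reporter group, at 25.5 ± 0.914 per 100 reads in nuclear peaks in Eomes-KO (SD, n = 2) against 18.0 ± 0.890 in Eomes-GFP+ (SD, n = 3). Nuclear reads outside peaks are not counted, so this ratio also depends on the share of nuclear reads that fall in peaks. The 4 mitochondrial peaks rose alike, the highest fold being 1.013 times the lowest, which argues against a variant or nuclear copy at 1 segment. The groups did not overlap, with a ratio of 1.413 and an exact permutation p of 0.1, the smallest that these libraries allow. More mitochondrial DNA per cell without Eomes and a difference in lysis cannot be told apart, because preparation dates are not given and each group may have been prepared apart. Neither can be told apart from a difference in the share of nuclear reads in peaks, which was not measured here.

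Very large changes lay at Cd4 and on chromosome 9 within 10 Mb of Eomes. Of 5 tested peaks that overlap the Cd4 span 5 rose, by 2.45 to 5.25 on the log2 scale (median 3.58), and extra copies of this DNA carried by the Cd4-driven Cre transgene cannot be told apart from a change in the use of Cd4 itself, because the extent of the transgene is not given. Within 10 Mb of Eomes 19 of 702 peaks changed at least 4-fold, at percentile 100 of 1961 windows, but 13 of them lay over 5 Mb away (123535747 to 124492014), the nearest lay 162027 bp from Eomes, and the 6 within 5 Mb were at percentile 99.3 of 2016 smaller windows. That excess is consistent with DNA of another strain linked to a modified Eomes allele, since windows on other chromosomes held at most 10 such peaks, but no variants were examined, and regulation of genes such as Ccr1 stays open. The window around Ifng ranked at percentile 99.9 with 10 such peaks, so a cluster of large changes is not unique to this region, and peaks at Ifng, Lag3 and Ccr1 may partly reflect DNA differences between the mice.

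Lower accessibility at type 1 and cytotoxic genes was weighed against 4 explanations. A trend of fold change with peak height as the whole cause is argued against, since loess offsets left a mean difference of -0.26 (camera adjusted p = 1.54e-05; adjusted p = 0.505 with an estimated correlation). So are DNA differences in the doubted regions near Eomes and Cd4 and within 10 Mb of Ifng as the whole cause, since without them it was -0.22 (camera adjusted p = 0.000133; adjusted p = 0.370 with an estimated correlation), against -0.26 before either change (adjusted p = 0.398 with an estimated correlation). Fewer CD8 T or NK-lineage cells in the knockout libraries stay open, although negative selection of naive CD4 T cells would remove such cells. The 37 peaks of their markers had a median log2 fold of -0.0819, and its bootstrap interval of -0.50 to 0.06 includes the -0.19 of the type 1 list. Named Cd8b1 peaks went both ways, from 238 to 114 and from 117 to 161 scaled reads. The latter lost its call with the DESeq2 Wald test (adjusted p = 0.0531). Of 2 Cd8a peaks 1 was lower and 0 higher, and the 6 CD8 T cell peaks had a median log2 fold of -0.65. Selection on the Eomes reporter and the loss of Eomes cannot be told apart for the 114 lower peaks, because whether the knockout cells were selected on it is not given.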

How the results depend on the processing

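The nuclear library size, TMM scaling, edgeR with TMM, pseudocounts, replicate block, removal of doubted regions, with or without the Ifng region, and pairs of a setting with an estimated correlation were chosen after the data were seen, and the other alternatives before. Of 160 called peaks among the 168 named, 147 kept their call under every alternative in which they were fitted, the minimum log2 fold not counted. Most of these were named for their small p, so their stability does not describe calls at large. Of the 26356 main calls, 19665 were also called with library size, 22488 with nuclear library size, 23597 with loess offsets and 15999 with the DESeq2 Wald test. Called peaks kept within 1.5 times their count except as follows. Library size gave 5115 higher and 24974 lower. The DESeq2 Wald test gave 16028 calls, 6297 of them higher. A false discovery rate of 0.01 left 7544 higher by its own construction, and a minimum log2 fold of 1 left 2924 peaks, 701 higher and 2223 lower, with 2 at the Eomes locus. Without the doubted regions (917 peaks near Eomes and Cd4, on Y, at the end of X, mitochondrial or unplaced) 11696 were higher and 14397 lower, and the type 1 list had 24 higher and 105 lower; without 631 peaks within 10 Mb of Ifng as well, it had 24 and 96. Replicate numbers of the columns did not pair the libraries (correlation of deviations -0.00936), and the replicate block, in which Eomes-GFP+ replicate 1 has no partner, gave 22609 calls, 9493 higher and 13116 lower. Gene lists called numbered 4, but 0 with an estimated correlation, alone or with gene-end peaks, links within 20 kb, loess offsets or either removal of doubted regions, and 2 with library size, nuclear library size, loess offsets or the replicate block. Leaving out 1 library gave 1 (without KO2) to 4. Where the estimate lay below the preset 0.01, calls lost with an estimated correlation need not reflect correlation between peaks. For the mitochondrial ribosome the estimate was -0.00525, yet the unadjusted camera p rose from 0.00499 to 0.0187. For inhibitory receptors it was 0.00422, and that p rose from 0.00618 to 0.0433. The other estimates lay above the preset, at 0.0563 for the type 1 list and 0.0277 for the respiratory chain. There the unadjusted camera p rose from 4.09e-07 to 0.0930 and from 0.00334 to 0.134, so correlation between peaks can account for part of these losses. Mean differences of lists whose call was lost were, for inhibitory receptors, 0.0833 with gene-end peaks, 0.11 within 20 kb and 0.14 with an estimated correlation. With an estimated correlation they were -0.26 for the type 1 list and 0.11 for both the respiratory chain and the mitochondrial ribosome. That setting enters only the p, so it cannot change a mean difference. Scaling by library size or nuclear reads moves nearly all log2 folds alike, so unchanged mean differences there were also fixed in advance. For the latter pair, in that order, they were 0.11 and 0.11 with library size, 0.11 and 0.11 with nuclear library size, 0.0890 and 0.0961 with loess offsets, and 0.11 and 0.11 with the replicate block. With an estimated correlation added, the inhibitory, respiratory chain, ribosome and type 1 lists had 0.0833, 0.13, 0.16 and -0.19 at gene ends, 0.11, 0.15, 0.14 and -0.26 within 20 kb, 0.14, 0.0890, 0.0961 and -0.26 with loess offsets, 0.14, 0.11, 0.11 and -0.26 without the doubted regions, and 0.14, 0.11, 0.11 and -0.22 without these and the Ifng region. Leaving out single libraries gave 0.12 to 0.15 for inhibitory receptors, 0.0956 to 0.12 for the respiratory chain and 0.11 to 0.11 for the mitochondrial ribosome. The log2 odds ratio at gene ends, 0.03 for higher and -0.71 for lower calls, turned to -2.13 and 0.31 with library size. In the same order it was -0.93 and -0.44 with nuclear library size and -0.89 and -0.35 with loess offsets. Without single libraries it ran from -0.33 to 0.24 for higher calls and from -0.96 to -0.47 for lower calls. The tallest Tcf7 peak turned to -0.0407 with library size. The cause was not tested where none is named. Motif content and the GC offset, alone and with the replicate block, were not run, since no genome sequence was used here. Without KO2 or KO3 the lone knockout library is assumed to vary like the other group. In data simulated with 50 peaks changed at each fold, 32% of those changed 1.2-fold were recovered. Far more peaks were called in the real data (39.4%), which loosens the Benjamini-Hochberg threshold. The simulated share therefore does not measure what was missed there. Whether depth, spread or the number of libraries limits recovery was not tested.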

Other observations

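All values and comparisons in this part were chosen after the results were seen. Lower calls took the largest share of peaks on chromosome 13, where 792 of 3124 peaks were lower and 512 higher, and on chromosome 6, where 918 of 3684 were lower and 571 higher. On X 184 of 1431 peaks were lower and 244 higher, and on Y 5 of 68 were lower and 21 higher. Most Y calls came from 41 peaks assigned to Gm52481, with 17 higher and 5 lower and log2 folds from -4.74 to 5.53. They do not describe Y as a whole. Among the 13394 tallest peaks, 3494 were higher and 1450 lower, with a median log2 fold of 0.06, while among the 13394 lowest 2043 were higher and 2846 lower, with a median of -0.04.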
